A study of Homo sapiens with 18 samples.

How the data were processed

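Messenger RNA was measured on 18 single-colour Illumina HumanHT-12 V4 BeadChip arrays, which carry 50-base probes for most annotated human transcripts. The arrays came from ES-2 cells, a human ovarian cancer line, stably transfected with an empty vector or with a vector for progesterone receptor A (PR-A) or B (PR-B). Per the labels' protocols, cells selected with G418 were held for 1 day in medium with charcoal-stripped serum and then given ethanol vehicle or the synthetic progestin R5020 for 24 h. The dose is written in the labels as 10e-8 M, a notation whose exponent is ambiguous. RNA was extracted with Trizol and a column kit with DNase treatment and labelled as biotinylated cRNA, per the labels' protocols. Each of the 6 groups had 3 arrays, and the labels gave every array its group and replicate number. One clone stood for each vector, so receptor isoform and clone cannot be separated by the design.

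The deposited raw table held, for each of 47323 probes, a summarised bead intensity on a linear scale that the authors had not normalized, and a detection p-value that ranks the probe against negative control beads, per the file headers. The steps of the deposited p-values implied 770 negative control beads. A second deposited table held the authors' processed values on a log2 scale. Their rank correlation with the raw intensity of the same array was 1 to the digits kept, and their sorted values differed between arrays by at most 0.0121 log2, as after quantile normalization. The software the authors used for that step is not given in the sources used here. Another 36 columns of bead counts and bead standard errors were not used. Because quantile normalization gives every array the same distribution, a change of total messenger RNA would not be visible in these values.

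R 4.3.3 was used with statmod 1.5.0 available, and a replicate block, where fitted, entered as fixed terms of the design. Raw intensities were corrected and normalized with neqc of limma 3.58.1. This step fits a background to the negative controls inferred from the detection p-values, adds an offset of 16, normalizes by quantiles and takes log2. The offset pulls the fold of dim probes towards 1. Background left in the signal does so more: without the correction, 311 of the 700 log2 changes past the threshold among the genes named by rule were smaller by over 1.5 times, and in the authors' processed values 312. The 92 spike-in control probes were left out, as were 3270 probes with no gene symbol, which were examined separately. Gene symbols of the array design were updated through the Entrez ID for 35672 probes and through the transcript accession for 85, while 8204 kept the symbol of the design. Probes detected at p under 0.05 on at least 3 of the 18 arrays were kept, 21548 in all. Each gene was represented by its kept probe with the highest mean over all arrays, which left 16227 genes. Of these, 4108 had more than 1 kept probe and 2084 carried only the older symbol of the design. Probes of near-identical families (the metallothioneins, SPANXB1 and SPANXB2, KRTAP2-1 and the pseudogene HBBP1) may read related transcripts and are uncertain at the level of the single gene. The array design places the CD24 probe on chromosome Y, so its reading is uncertain at that level too.

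A linear model with 1 mean per group was fitted to all 18 arrays with lmFit and moderated with eBayes, both of limma, so that the groups shared 1 estimate of the spread per gene. There were 10 comparisons: R5020 against vehicle in each of the 3 clones, the clones against each other in vehicle, PR-B against PR-A under R5020, and the 3 differences in R5020 response between clones. Tests were two-sided and p-values were adjusted by the Benjamini-Hochberg method over the 16227 genes of a comparison, with 0.05 as the threshold. Every adjusted p of a single gene given here is from limma. Changes are log2 differences of group means with the standard error (SE) of the fit, and group levels are normalized log2 intensities with the standard deviation (SD) of 3 arrays. Where a probe was undetected on all 3 arrays of the dimmer group, the fold is given as "at least", computed against the higher, array by array, of the lowest detected signal and the probe's own signal. The number of arrays limits the precision. The labels state that cells were treated and analysed in triplicate without saying whether cultures were independent, so p-values measure the spread between these samples, which may be technical.

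The genes to be named were fixed by rule before the data were examined, as were 18 gene lists, the designs and the alternatives. The rule took PGR, FOXO1 and CDKN1A everywhere. It added the 10 largest rises and 10 largest falls (8 and 8 between clones) past the threshold with no overlap of the 3 and 3 arrays, passing over uncharacterised loci. From each list it took up to 4 members with the largest change past the threshold, or up to 2 with the lowest p where none passed. The lists hold 490 genes, of which 393 were tested. They cover the progestin and glucocorticoid response, FOXO targets, p53 targets, senescence secretory factors, S phase and replication, mitosis, interferon response, NF-kB targets, sterol and lipid synthesis, metallothioneins, extracellular matrix, epithelial identity, hypoxia response, unfolded protein and amino acid stress, MAPK and immediate early genes, decidualization, leukocyte markers, and markers of fibroblasts, mesothelium and endothelium. Some genes sit in several lists: 9 are shared by the senescence and NF-kB lists and 4 by the FOXO and p53 lists. Lists were tested with camera of limma, which compares a list with all other genes, at a preset correlation of 0.01 and with an estimated correlation beside it, adjusted over the 18 lists of a comparison. Of the 180 list tests 60 passed the threshold, and 40 of these also did with an estimated correlation. For those 40 the adjusted p was larger with an estimated correlation, and mostly the preset value alone is printed.

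The gene fits were tested on simulated log2 values of the 16227 genes. Each gene had its mean over all arrays and independent normal noise of its moderated spread. Far fewer genes were changed than in the real PR-B response. Background correction, normalization and the detection filter were not rerun, so the rates hold for the fits alone. For the PR-B response to R5020 it recovered 48 of 75 genes changed 1.5-fold, 56 of 57 changed 2-fold and 68 of 68 changed 4-fold, and called 7 of 16027 unchanged genes. For the difference between the PR-B and PR-A responses it recovered 22 of 62, 59 of 74 and 64 of 64, and called 14 unchanged genes. Alternatives covered the normalization (cyclic loess, no background correction, a common median, the authors' processed values), the detection filter, the probe rule, the replicate number as a block, fits on only the arrays compared, array weights, eBayes with trend and robust options, other list tests and leaving out each array. The array barcodes were not used here, so chip was not modelled. The reference table used for symbols names no build shared with the array, so positions are those of the probe on its transcript as the array design gives them.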

Results

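Gene expression was compared in ES-2 ovarian cancer cells that carried an empty vector, PR-A or PR-B, each with 3 vehicle arrays and 3 arrays after 24 h of R5020, a synthetic ligand of the progesterone receptor. PR-A and PR-B are made from the single gene PGR, and PR-A lacks the first part of the PR-B protein. By its title the series is concerned with how the isoforms differ in the genes they control, with cell senescence, and with the transcription factor FOXO1 in both. Between 38.9% and 42.2% of the 47323 probes were detected on an array, and median raw intensity ran from 91.95 to 114.5. Within groups, arrays correlated at 0.9889 to 0.996 across genes, and no pair of arrays held identical values. The first principal component (37.7% of the variance) separated the PR-A clone from the PR-B clone, and the second (27.9%) separated R5020 from vehicle in both receptor clones. On the second component the mean of the empty-vector arrays was 24.7 in vehicle and 24.1 under R5020. PR-A arrays moved from 5.5 to -21 and PR-B arrays from 3 to -36.3.

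**Figure D1:**
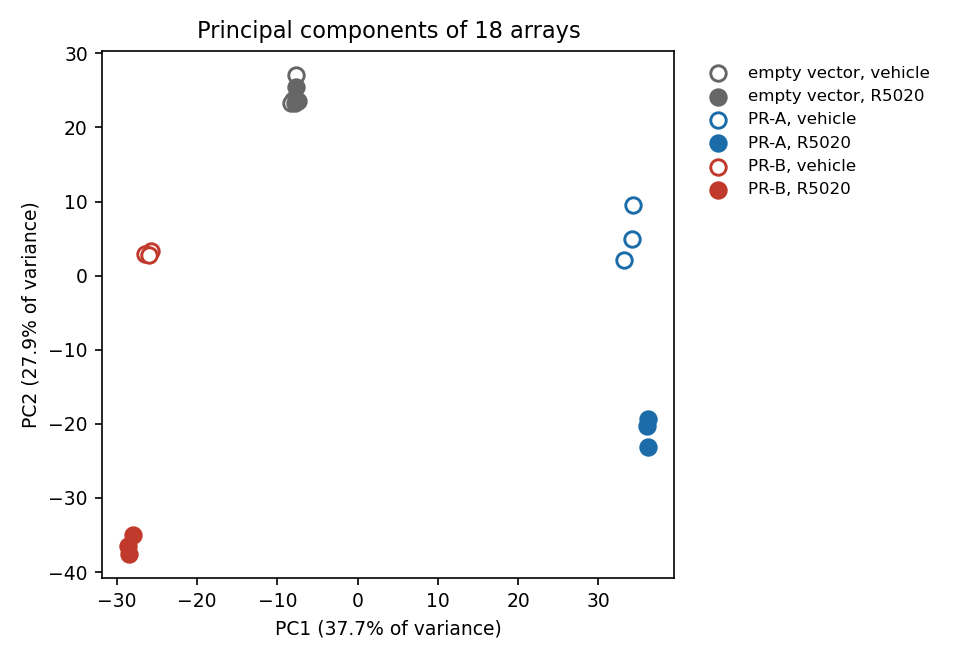
First and second principal components of the 18 arrays over the 16227 genes tested, with 1 point per array, coloured by clone, filled for R5020 and open for vehicle. R5020 arrays of the PR-A and PR-B clones lie below their vehicle arrays on the second component, while the empty-vector arrays of both treatments lie together.

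PGR itself was undetected on all 6 empty-vector arrays, with levels of 4.33 (SD 0.04) in vehicle and 4.42 (SD 0.06) under R5020. It reached 9.46 (SD 0.18) in PR-A and 8.71 (SD 0.02) in PR-B cells in vehicle, at least 24.2-fold and at least 14.3-fold above the empty vector (adjusted p = 2.24e-16 and 1.59e-15). Without background correction these log2 differences of 5.13 and 4.37 were 3.102 and 2.448. R5020 raised PGR signal by 0.50 ± 0.09 in PR-A cells (1.41-fold, adjusted p = 0.00098) and by 1.77 ± 0.09 in PR-B cells (3.4-fold, adjusted p = 1.58e-10). The PR-A rise did not pass with a common median (adjusted p = 0.0977, the highest over the alternatives, from 4.83e-05). The rise was larger in PR-B cells by 1.27 (adjusted p = 5.9e-06). PR-B cells thus held less PGR signal than PR-A cells in vehicle (-0.76, adjusted p = 4.45e-06) and more under R5020 (0.51, adjusted p = 0.000208). The PGR probe on chromosome 11, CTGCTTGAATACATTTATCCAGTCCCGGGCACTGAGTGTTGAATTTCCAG, starts at position 4124 of its transcript. It lies in sequence shared by both isoforms, so it does not tell them apart.

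**Figure D2:**
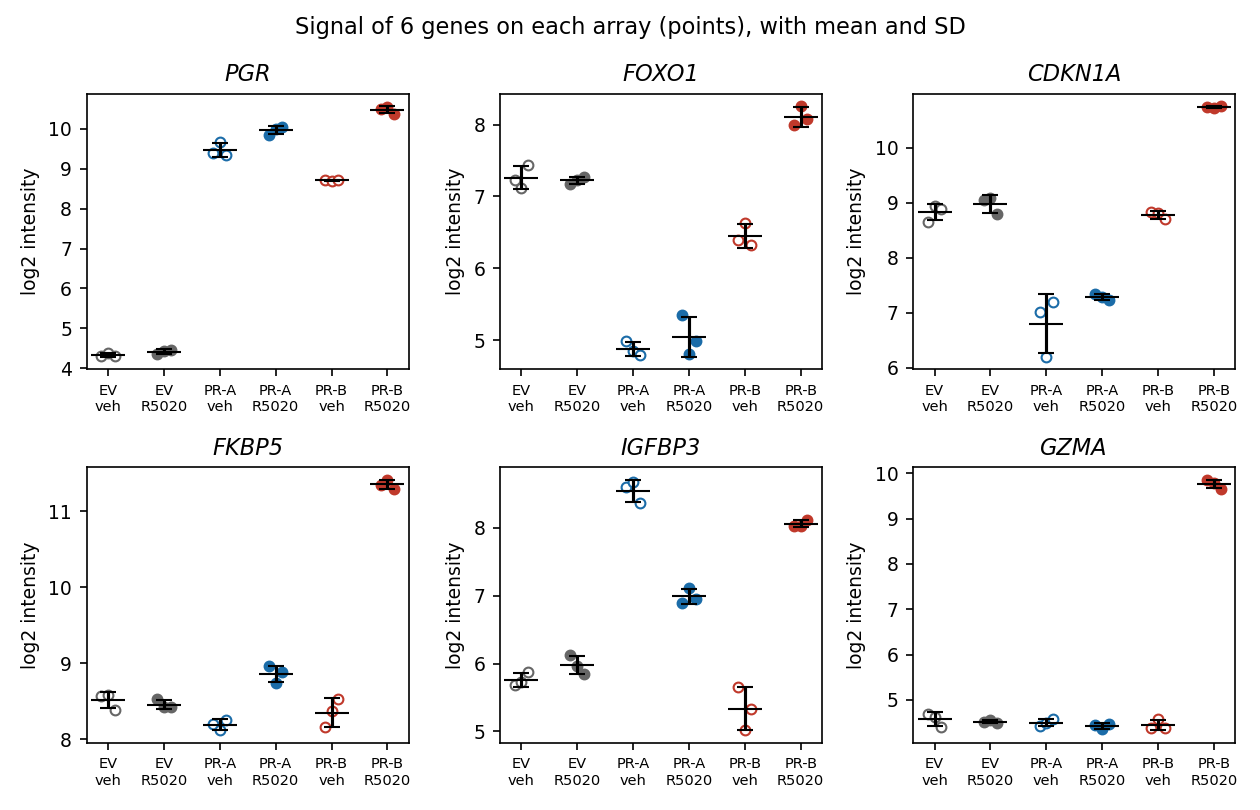
Normalized log2 intensity of PGR, FOXO1, CDKN1A, FKBP5, IGFBP3 and GZMA in the 6 groups, with points for single arrays and bars for the mean and SD of 3 arrays. After R5020 all 6 rose in PR-B cells, IGFBP3 fell in PR-A cells, and none passed the threshold in empty-vector cells.

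R5020 in empty-vector cells addressed effects of the ligand without introduced receptor. FOXO1, a forkhead transcription factor, stood at 7.26 (SD 0.16) in vehicle and 7.23 (SD 0.05) under R5020 (adjusted p = 1). CDKN1A, which encodes the cell-cycle inhibitor p21, stood at 8.83 (SD 0.15) and 8.99 (SD 0.16, adjusted p = 0.987). PGR was not detected in either group. ANGPTL4, a secreted regulator of lipoprotein lipase, changed by 0.23 (adjusted p = 0.944), BCL2L11, which encodes the cell death protein BIM, by 0.35 and BMP2, a bone morphogenetic protein, by -0.37 (adjusted p = 0.929 for both). Limma called 0 of 16227 genes, with a smallest adjusted p of 0.340. At an unadjusted p under 0.05 there were 857 genes, where 811 are expected by chance. With no background correction, with the authors' processed values, or with the trend and robust options, 1 gene passed. None of the 18 lists passed, the lowest camera adjusted p being 0.654.

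In PR-A cells R5020 raised CCN4, a matricellular protein induced by WNT signalling, from 4.98 to 9.45, a log2 change of 4.48 ± 0.11 (adjusted p = 1.1e-13, detected on 2 of 3 vehicle arrays). MAP2, a microtubule-associated protein of neurons, rose by 3.72 ± 0.13 (detected on 2 of 3 vehicle arrays), NDRG1, a stress- and hypoxia-induced gene, by 2.91 ± 0.1 (adjusted p = 2.98e-12 for both). VCAM1, a cell adhesion molecule, rose by 2.9 ± 0.14 and OXTR, the oxytocin receptor, by 2.26 ± 0.1. The cytokine gene IL1B fell by 3.33 ± 0.16 (adjusted p = 1.65e-10). Falls were also seen for TP63, a transcription factor of the p53 family (-2.44 ± 0.12), FOXA2, a forkhead factor (-2.24), the protease inhibitor gene SERPINB2 (-2.28) and ANGPT1, a ligand of the TIE2 receptor (-2.11). FOXO1 was near background in these cells (detected on 1 of 3 vehicle arrays) and changed by 0.17 ± 0.13 (adjusted p = 0.425). CDKN1A changed by 0.48 ± 0.18 (adjusted p = 0.0782), with a vehicle SD of 0.53. Without PR-A vehicle array 2, where CDKN1A stood lowest at 6.2, the change was 0.181 (adjusted p = 0.33), and without array 3 it was 0.683 (adjusted p = 0.0114), these being the highest and lowest p over the alternatives. With the authors' processed values it passed narrowly (0.279, adjusted p = 0.0499).

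Several groups of genes moved together in PR-A cells. Of 30 tested genes of the progestin and glucocorticoid response, 11 rose and 2 fell, or 13 and 2 adjusted over the list alone (camera adjusted p = 1.65e-05). Among them were CRISPLD2 (1.9), the transcription factor CEBPD (1.27 ± 0.1) and TSC22D3, which encodes the glucocorticoid-induced leucine zipper (1.22 ± 0.11), while EDN1, the precursor of endothelin 1, fell (-1.77). In the hypoxia list 11 of 27 rose and 2 fell, or 12 and 2 adjusted over the list alone (adjusted p = 2.15e-05). CA12, a carbonic anhydrase, stood at 1.49 and P4HA2, a collagen prolyl hydroxylase, at 1.33. The metal-binding metallothioneins rose in 5 of 6, also 5 adjusted over the list alone (adjusted p = 3.57e-06), led by MT1G (1.43) and MT1X (1.24). MAPK and immediate early genes moved down: 14 of 25 fell and 1 rose, or 16 and 1 adjusted over the list alone (adjusted p = 5.72e-07). Among them were PHLDA1 (-1.44), EGR1 (-1.18) and HBEGF (-0.85), with the phosphatase gene DUSP5 higher by 0.92. Senescence secretory factors had 9 falls and 3 rises in 26, or 11 and 5 adjusted over the list alone (adjusted p = 0.00415). CXCL8 (-1.73), the collagenase gene MMP1 (-1.48) and IGFBP3 (-1.56 ± 0.13), an insulin-like growth factor binding protein, fell. The mean of that list was -0.348 and its median -0.016, so the shift rests on few large falls.

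Other lists in PR-A cells passed less firmly. In the extracellular matrix list 12 of 33 rose and 6 fell, or 15 and 6 adjusted over the list alone (adjusted p = 0.00239, and adjusted p = 0.0619 with an estimated correlation). THBS1 (1.86) and COL1A1 (1.71 ± 0.1) led it. FOXO targets had 8 rises and 4 falls in 33, or 11 and 5 adjusted over the list alone (adjusted p = 0.0275), with IRS2, an insulin receptor substrate, at 1.56 and the repressor BCL6 at 1.34. Without PR-A vehicle array 3 or PR-A R5020 array 2 the FOXO adjusted p was 0.0649 or 0.0532, in a range of 0.00594 to 0.0649 over all alternatives. S phase genes had 9 rises and 2 falls in 38, or 10 and 2 adjusted over the list alone (adjusted p = 0.0129, and adjusted p = 0.251 with an estimated correlation), such as the thymidine kinase gene TK1 (0.54 ± 0.09). With a common median the S phase adjusted p was 0.0741. Stress genes of the unfolded protein list had 7 rises and 1 fall in 25, or 9 and 1 adjusted over the list alone (adjusted p = 0.0217, and adjusted p = 0.434 with an estimated correlation), with SLC7A5, an amino acid transporter, at 0.8. Without PR-A vehicle array 2 its adjusted p was 0.151, the highest of a range from 0.00264.

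The remaining lists did not pass in PR-A cells. P53 targets had 5 rises and 1 fall in 23 (6 and 4 adjusted over the list alone, adjusted p = 0.232), among them GADD45A (0.88). Interferon genes had 5 rises and 2 falls in 26 (7 and 2 adjusted over the list alone, adjusted p = 0.208), and decidualization genes 1 and 5 in 21 (1 and 6 adjusted over the list alone, adjusted p = 0.0854). The other lists had the same counts when adjusted over the list alone. Mitosis genes had 1 rise and 2 falls in 35 (adjusted p = 0.931). Sterol genes had 5 and 2 in 28 (adjusted p = 0.258), NF-kB targets 4 and 4 in 23 (0.958) and epithelial genes 2 and 1 in 8 (0.668). Leukocyte markers had 2 rises and 2 falls in 8 (0.931), and markers of fibroblasts, mesothelium and endothelium 3 and 2 in 14 (0.634). Altogether R5020 raised 1183 genes and lowered 1128 in PR-A cells, 14.2% of those tested, with 243 changed at least 2-fold. Fits on only the 6 arrays compared called 1061 genes, and normalization to a common median gave 481 higher and 941 lower.

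In PR-B cells the largest rise was that of GZMA, which encodes the cytotoxic protease granzyme A: it went from an undetected 4.45 to 9.77, a log2 change of 5.32 ± 0.09 (at least 29-fold, adjusted p = 1.53e-16). CEBPD rose by 3.61 ± 0.1 (adjusted p = 1.26e-13), FOXO4, a forkhead factor, by 3.31 ± 0.14 (adjusted p = 2.03e-11), the prostaglandin receptor gene PTGER4 by 3.31 ± 0.09 and THBS1 by 3.06 ± 0.09. FOXO1 rose by 1.66 ± 0.13, from 6.45 (SD 0.16) to 8.11 (SD 0.14, 3.16-fold, adjusted p = 3.65e-08), and by 1.062 in the authors' processed values. CDKN1A rose by 1.96 ± 0.18, from 8.78 (SD 0.08) to 10.75 (SD 0.02, 3.9-fold, adjusted p = 2.08e-07). IL1B fell by 2.62 ± 0.16 (at least 5.19-fold, adjusted p = 1.56e-09), and so did TP63 (-2.47 ± 0.12), SERPINB2 (-2.36) and COL17A1, a hemidesmosome collagen (-2.2).

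Both lists of cycling-cell genes fell in PR-B cells. In the S phase list 26 of 38 fell and 0 rose, or 30 and 0 adjusted over the list alone (camera adjusted p = 1.94e-12, and adjusted p = 0.00455 with an estimated correlation). They included EXO1, a DNA repair exonuclease (-0.76 ± 0.09), cyclin E2 gene CCNE2 (-0.72 ± 0.1), CHAF1A (-0.69) and the phosphatase gene CDC25A (-0.66). In the mitosis list 30 of 35 fell and 0 rose, or 31 and 0 adjusted over the list alone (adjusted p = 4.3e-13, and adjusted p = 2.41e-05 with an estimated correlation). Among them were MKI67, which encodes the proliferation marker Ki-67 (-0.72 ± 0.14), the mitotic kinase gene AURKB (-0.66 ± 0.09) and the separase gene ESPL1 (-0.58). The mean over array means of the S phase list went from 9.19 (SD 0.023) to 8.76 (SD 0.036), and that of the mitosis list from 9.87 (SD 0.003) to 9.45 (SD 0.021). FOXO targets went up, with 21 of 33 higher and 2 lower, or 22 and 2 adjusted over the list alone (adjusted p = 5.73e-10). IRS2 rose by 2.9 ± 0.09, DEPP1, an autophagy regulator, by 2.12 and GABARAPL1, an autophagosome protein, by 1.78. For p53 targets 9 of 23 rose and 3 fell, also 9 and 3 adjusted over the list alone (adjusted p = 0.00719), led by TP53I3 (2.31 ± 0.11) with TP53INP1 (1.01) and GADD45A (0.72). CDKN1A is in both of these lists.

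The progestin and glucocorticoid list had 16 rises and 2 falls in 30, or 19 and 2 adjusted over the list alone (adjusted p = 2.69e-10). FKBP5, a chaperone partner of steroid receptors, rose 7.99-fold (3.00 ± 0.1), TSC22D3 by 3.06 ± 0.11 and TIPARP by 2.68 ± 0.13. Sterol and lipid synthesis genes had 12 rises and 1 fall in 28, or 14 and 1 adjusted over the list alone (adjusted p = 0.000179), such as MSMO1 (0.94 ± 0.12) and NSDHL (0.92). In the hypoxia list 11 of 27 rose and 4 fell, or 13 and 4 adjusted over the list alone (adjusted p = 0.00013), with NDRG1 at 2.57 and the glucose transporter gene SLC2A3 at 1.88. Metallothioneins rose in 3 of 6, also 3 adjusted over the list alone (adjusted p = 0.000451), with MT1G at 1.93. Extracellular matrix genes had 14 rises and 9 falls in 33, or 15 and 9 adjusted over the list alone (adjusted p = 0.0145, and adjusted p = 0.117 with an estimated correlation). They ranged from COL6A3 (2.96 ± 0.08) to the tenascin gene TNC (-1.87), and lost the call under the stricter detection filter (adjusted p = 0.0633, the highest of a range from 0.00152). MAPK and immediate early genes had 13 falls and 5 rises in 25, or 14 and 7 adjusted over the list alone (adjusted p = 0.00719, and adjusted p = 0.0567 with an estimated correlation). HBEGF stood at -1.53, FOSL1 at -1.43 and FOS at 1.38.

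Senescence secretory factors did not pass as a list in PR-B cells: 4 of 26 rose and 9 fell, or 5 and 9 adjusted over the list alone (adjusted p = 0.0612). IGFBP3 rose 6.6-fold (2.72 ± 0.13) and ANGPTL4 by 2.27, while the stromelysin gene MMP3 fell (-1.85). Interferon genes had 12 rises and 5 falls in 26 (13 and 8 adjusted over the list alone, adjusted p = 0.104), among them IFIT1 (1.25) and HERC5 (-1.4). NF-kB targets had 3 and 5 in 23 (5 and 7 adjusted over the list alone, adjusted p = 0.671). Epithelial genes had 3 and 1 in 8 (3 and 2 adjusted over the list alone, adjusted p = 0.0798), and among them the mucin gene MUC1 rose by 2.83 ± 0.1. Leukocyte markers had 0 rises and 2 falls in 8 (0 and 3 adjusted over the list alone, adjusted p = 0.184). With the same counts when adjusted over the list alone, stress genes had 7 and 4 in 25 (adjusted p = 0.502), decidualization genes 5 and 7 in 21 (0.758) and markers of fibroblasts, mesothelium and endothelium 4 and 3 in 14 (0.596). In all, R5020 raised 1941 genes and lowered 1926 in PR-B cells, 23.8% of those tested, with 498 changed at least 2-fold. Normalized to a common median, the split was 2248 higher and 755 lower.

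**Figure D3:**
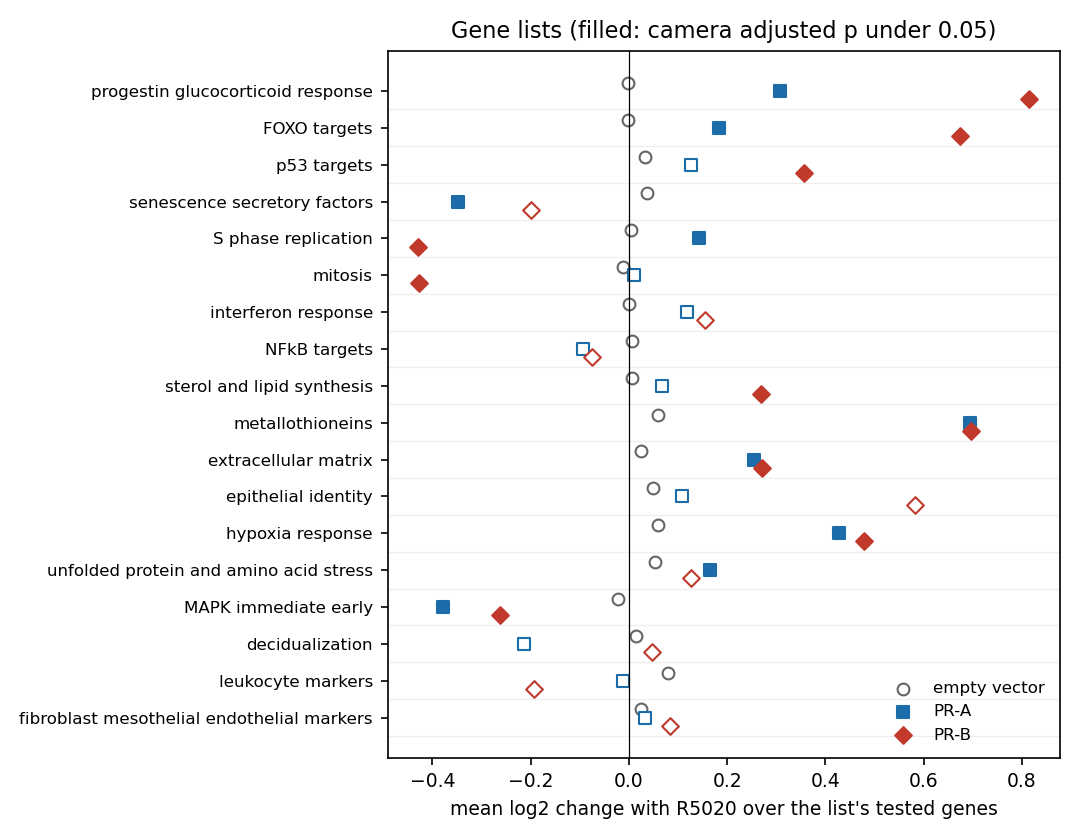
Mean log2 change after R5020 of each of the 18 gene lists in empty-vector, PR-A and PR-B cells, with filled symbols where camera's adjusted p was under 0.05. The S phase and mitosis lists stood at -0.429 and -0.427 in PR-B cells, and at 0.142 and 0.011 in PR-A cells.

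The difference between the PR-B and PR-A responses was tested directly. GZMA (5.4 ± 0.13 higher response in PR-B cells, adjusted p = 3.83e-14) and IGFBP3 (4.28 ± 0.19, adjusted p = 1.94e-10) differed most, followed by C1QTNF1 (3.77), SPINK13 (3.77), FOXO4 (3.07) and the actin-severing protein gene GSN (2.73). GZMA, C1QTNF1, SPINK13 and GSN were undetected in PR-B vehicle cells, so the size of these differences is uncertain. FOXO1 rose more in PR-B cells by 1.49 ± 0.18 (adjusted p = 5.12e-05), a size uncertain too, since it was detected on 1 of 3 vehicle and 2 of 3 R5020 arrays of PR-A cells, and CDKN1A by 1.48 ± 0.25 (adjusted p = 0.000983). VCAM1 (-2.54 ± 0.2, adjusted p = 2.53e-07) and CCN4 (-1.94 ± 0.16, adjusted p = 6.93e-07, undetected in PR-B vehicle cells) rose more in PR-A cells. TGFBI, a matrix protein induced by TGF-beta, differed by -1.86 ± 0.12 (adjusted p = 4.27e-08). IGFBP3 fell in PR-A and rose in PR-B cells (-1.56 and 2.72), as did the early growth response gene EGR1 (-1.18 and 0.77). TGFBI (0.87 and -0.99) and ENPP2, which encodes autotaxin (1.07 and -0.61), went the other way. The clones started apart for IGFBP3, at 8.36 to 8.68 on PR-A vehicle arrays and 5.02 to 5.66 on PR-B vehicle arrays.

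Cell-cycle genes differed as groups. In the S phase list 26 of 38 genes were lower and 0 higher in their PR-B response, or 33 and 0 adjusted over the list alone (camera adjusted p = 2.05e-19, and adjusted p = 0.000845 with an estimated correlation). The mitosis list had 16 lower and 0 higher of 35, or 29 and 0 adjusted over the list alone (adjusted p = 1.69e-13, and adjusted p = 2.31e-05 with an estimated correlation). CDT1, a replication licensing factor, differed by -1.18 ± 0.18 and the kinase gene PLK1 by -1.06 ± 0.19. FOXO targets were higher for 12 and lower for 0 of 33, or 13 and 1 adjusted over the list alone (adjusted p = 2.95e-07), with DEPP1 at 2.09 and IGFBP1, undetected in PR-B vehicle cells, at 1.78. Progestin and glucocorticoid genes were higher for 11 and lower for 3 of 30, or 14 and 5 adjusted over the list alone (adjusted p = 5.45e-06), with FKBP5 at 2.33 ± 0.14. Sterol genes were higher for 4 of 28, or 5 adjusted over the list alone, with 0 lower in either count (adjusted p = 0.012, and adjusted p = 0.0965 with an estimated correlation), such as MSMO1 (1.18). The mean level of this list in PR-B against PR-A cells was -0.217 in vehicle and -0.015 under R5020. Epithelial genes were higher for 2 of 8, also 2 adjusted over the list alone (adjusted p = 0.05, and adjusted p = 0.148 with an estimated correlation), these being MUC1 (2.08) and CD24 (1.65, detected on 2 of 3 arrays in each PR-A group). That list rests on this pair, with a mean of 0.474 and a median of 0.085, and its adjusted p ran from 0.000309 to 0.104 over the alternatives. The adjusted p rose above the threshold with cyclic loess (0.0733), with no detection filter (0.104), and with 1 of 6 arrays left out: PR-A vehicle array 1 (0.0729) or 3 (0.069), PR-A R5020 array 1 (0.062), PR-B vehicle array 3 (0.076), or PR-B R5020 array 2 (0.0505) or 3 (0.062).

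The response differed past the threshold for 1648 genes, with 864 higher and 784 lower in PR-B cells, and 1057 higher and 137 lower after scaling to a common median, which moved the median of all genes by 0.162. Between the lists of R5020-changed genes, 609 rose in both clones and 564 fell in both, against 141.5 and 133.9 for independent lists (Fisher's exact test, two-sided, odds ratios 10.92 and 10.08, p = 2.74e-272 and 4.23e-243). These 2 comparisons share no arrays, but they share the estimate of the spread per gene. Fisher's test also counts genes as independent, which they are not, so its p-values overstate the certainty. Another 90 genes were called in opposite directions. For all 90 the difference in response passed the threshold, which the way they were chosen made nearly certain. Across genes, which are not independent replicates, log2 changes correlated at r = 0.492 (rho = 0.315). Of the 1173 genes changed the same way, 755 (64.4%) changed more in PR-B cells, with median sizes of 0.57 in PR-A and 0.685 in PR-B. This count compares estimates alone, whether or not the difference in response of a gene passed the threshold. Of the 2604 genes called in PR-B but not in PR-A cells, the response differed for 949, and of the 1048 called in PR-A but not in PR-B for 297. Same-direction overlap came to 675 genes with a common median and 674 with fits on only the arrays compared.

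**Figure D4:**
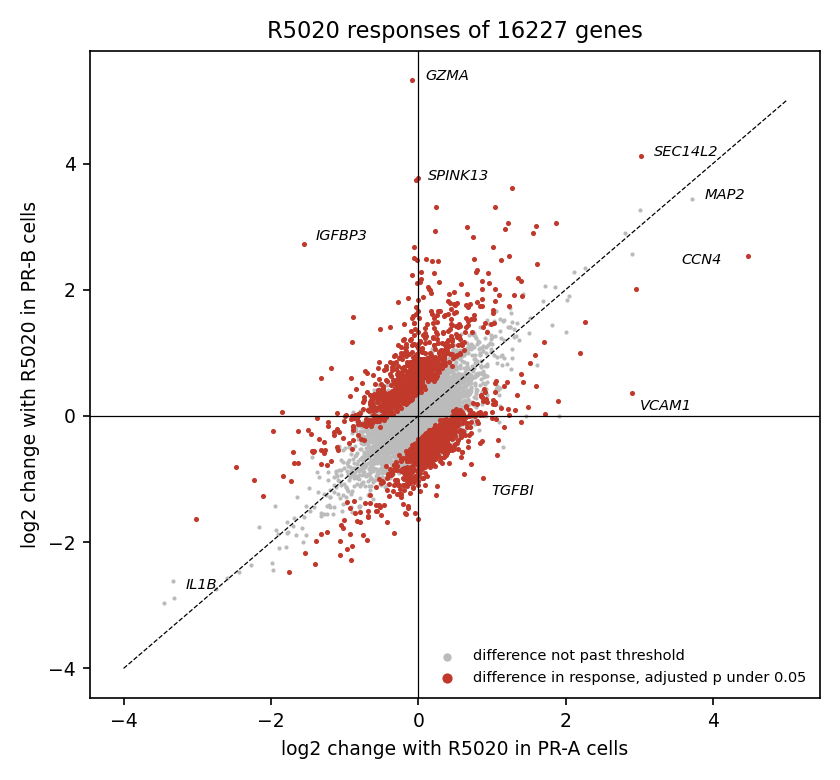
Log2 change after R5020 in PR-A cells (horizontal axis) against PR-B cells (vertical axis) for 16227 genes, with genes whose response differed past the threshold in red and the line of equal response dashed. The 1648 red genes lie off that line on either side, and the correlation across all genes was 0.492.

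Set against the empty-vector response, the PR-A response had CCN4 (4.51), MAP2 (3.62) and NDRG1 (2.98) among the largest excesses and IL1B (-3.47), the long noncoding RNA UCA1 (-2.62) and TP63 (-2.24) among the largest deficits. CCN4 was detected on 1 of 3 arrays in each empty-vector group and 2 of 3 in PR-A vehicle. MAP2 was undetected in empty-vector vehicle cells and PGR in both empty-vector groups, so the sizes for these genes are uncertain. PGR (0.42, adjusted p = 0.0691), FOXO1 (0.21, adjusted p = 0.602) and CDKN1A (0.33, adjusted p = 0.537) did not pass. The PGR difference passed under 5 alternatives: without PR-A vehicle array 2 (0.516, adjusted p = 0.00827), with array weights (adjusted p = 0.00932), without background correction (0.0202), with the authors' processed values (0.0234) and with the stricter filter (0.0412). Its highest adjusted p over the alternatives was 0.471. Progestin and glucocorticoid genes were higher for 11 and lower for 1 of 30, or 11 and 2 adjusted over the list alone (adjusted p = 2.22e-05), among them CRISPLD2 and CEBPD. Metallothioneins were higher for 3 of 6, or 5 adjusted over the list alone (adjusted p = 1.72e-05). Also higher were hypoxia genes (6 and 2 of 27, or 9 and 2 adjusted over the list alone, adjusted p = 0.000268) and extracellular matrix genes (10 and 5 of 33, or 13 and 6 adjusted over the list alone, adjusted p = 0.00425, and adjusted p = 0.0832 with an estimated correlation). Lower were MAPK genes (1 higher and 7 lower of 25, or 1 and 12 adjusted over the list alone, adjusted p = 1.15e-05) and senescence factors (1 and 8 of 26, or 1 and 9 adjusted over the list alone, adjusted p = 0.000942). FOXO targets (6 and 2 of 33, or 9 and 4 adjusted over the list alone, adjusted p = 0.0412, and adjusted p = 0.0568 with an estimated correlation) also passed. That call was lost without empty-vector R5020 array 1, PR-A vehicle array 2 or 3, or PR-A R5020 array 2 (adjusted p of 0.0738, 0.0775, 0.0792 and 0.0708, the range over alternatives starting at 0.0218). S phase genes had 1 higher and 0 lower of 38, also 1 and 0 adjusted over the list alone (adjusted p = 0.0242, and adjusted p = 0.307 with an estimated correlation). Their mean of 0.137 went to -0.034 with a common median, which moved the median of all genes to -0.11, so the list stayed above it. Without PR-A vehicle array 2 the adjusted p was 0.0811. In total 475 genes were higher and 482 lower, or 177 and 436 with a common median, which moved the median of all genes by -0.116.

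The PR-B response exceeded the empty-vector response for GZMA (5.37), SEC14L2 (4.18), CEBPD (3.37), PTGER4 (3.31), FOXO4 (3.25), FKBP5 (3.06) and IRS2 (3.00), among others. It fell short for KRTAP2-1 (-2.91), IL1B (-2.76), TP63 (-2.28) and SERPINB2 (-2.27), among others. GZMA and SEC14L2 were undetected in PR-B vehicle cells, IL1B in PR-B cells under R5020 and PGR in empty-vector cells, so the sizes for these genes are uncertain. PGR (1.68, adjusted p = 7.15e-08), FOXO1 (1.70, adjusted p = 4.8e-06, or 1.088 in the authors' processed values) and CDKN1A (1.81, adjusted p = 7.13e-05) all passed. Progestin and glucocorticoid genes were higher for 14 and lower for 1 of 30, or 16 and 2 adjusted over the list alone (adjusted p = 5.11e-11). FOXO targets were higher for 17 and lower for 2 of 33, or 21 and 3 adjusted over the list alone (adjusted p = 4.3e-10), and p53 targets for 6 and 1 of 23, or 8 and 3 adjusted over the list alone (adjusted p = 0.0147). Sterol synthesis genes were higher for 5 and lower for 0 of 28, or 10 and 0 adjusted over the list alone (adjusted p = 0.000734). Metallothioneins were higher for 2 of 6, also 2 adjusted over the list alone (adjusted p = 0.00154). Higher too were hypoxia genes (9 and 4 of 27, or 11 and 4 adjusted over the list alone, adjusted p = 0.000891) and extracellular matrix genes (13 and 9 of 33, or 14 and 9 adjusted over the list alone, adjusted p = 0.0202, and adjusted p = 0.129 with an estimated correlation). Lower were S phase genes (21 of 38 lower, 22 adjusted over the list alone) and mitosis genes (17 of 35, 22 adjusted over the list alone), both with 0 higher (adjusted p = 5.11e-11 for both). With an estimated correlation camera's adjusted p was 0.0071 for S phase and 7.05e-05 for mitosis genes. MAPK genes were lower for 10 and higher for 4 of 25, or 10 and 5 adjusted over the list alone (adjusted p = 0.0129, and adjusted p = 0.0714 with an estimated correlation). Senescence factors were lower for 9 and higher for 4 of 26, also 9 and 4 adjusted over the list alone (adjusted p = 0.0416, and adjusted p = 0.0996 with an estimated correlation). The senescence call was lost without empty-vector R5020 array 1 (0.0504), PR-B vehicle array 1 (0.0569) or PR-B R5020 array 2 (0.0622), the range over alternatives starting at 0.0158. In total 1108 genes were higher and 1062 lower, or 892 and 456 with a common median.

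Both of these differences use the same empty-vector arrays. Their log2 values correlated at 0.549 across genes, where simulated unchanged groups against shared controls gave 0.499, and their covariance was 0.0831 against a simulated 0.0217. The pair had 262 genes higher and 289 lower in common and 17 opposite, against 32.4 and 31.5 for independent lists. The simulated overlap of 0 cannot serve as a yardstick here, since the simulated groups were unchanged. Part of the excess may come from the shared controls.

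Before any ligand, PR-A cells differed widely from empty-vector cells. Besides PGR, they had more IGFBP1, an insulin-like growth factor binding protein (3.98, at least 11.8-fold), FGF13 (at least 7.35-fold), the neurotrophin receptor gene NGFR (at least 7.33-fold), CRISPLD2 (2.94) and IGFBP3 (2.78). They had less THBS2, a matrix glycoprotein (-4.05 ± 0.1, adjusted p = 2.12e-14, detected on 1 of 3 PR-A arrays), THY1, a surface glycoprotein of fibroblasts (-3.89, at least 12.4-fold), the tight junction gene CLDN11 (-3.49) and the kinase gene LYN (-3.38). FOXO1, detected on 1 of 3 PR-A arrays, was lower by a size that is uncertain so near background (-2.39, adjusted p = 3.22e-10, and from -2.568 to -1.08 over the alternatives). CDKN1A was 4.07-fold lower (-2.03, adjusted p = 1.46e-07). Hypoxia genes were higher for 14 and lower for 3 of 27, also 14 and 3 adjusted over the list alone (camera adjusted p = 0.00173), with CA9 at least 2.91-fold higher. MAPK genes were lower for 11 and higher for 0 of 25, or 12 and 0 adjusted over the list alone (adjusted p = 0.000322), with EGR1 at -1.13. Extracellular matrix genes (15 higher and 6 lower of 33, or 16 and 8 adjusted over the list alone) and stress genes (2 and 14 of 25, or 3 and 14 adjusted over the list alone) passed with adjusted p = 0.0109 and 0.00332, but had adjusted p = 0.242 and 0.497 with an estimated correlation. Examples were COL1A1 (2.29) and SLC7A5 (-0.93). Markers of fibroblasts, mesothelium and endothelium had 3 higher and 1 lower of 14, also 3 and 1 adjusted over the list alone (adjusted p = 0.482). There were 2105 genes higher and 2194 lower, or 872 and 3086 with a common median, which moved the median of all genes by -0.112. As 1 clone stood for each vector, clone and receptor cannot be told apart here or in the other comparisons between clones.

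PR-B cells in vehicle had more IL13RA2, a decoy receptor for interleukin 13 (4.94 ± 0.11, 30.6-fold, adjusted p = 1.78e-15), the desmosome gene DSG2 (3.84, at least 11.5-fold) and CD24 (2.89) than empty-vector cells. They had less of the protease CTSK (-3.04, at least 5.97-fold), the lactate transporter SLC16A3 (-2.83, detected on 2 of 3 PR-B arrays) and the transcription factor TFAP2C (at least 3.91-fold). FOXO1 was lower (-0.82, adjusted p = 0.000252, or -0.47 without background correction), and CDKN1A differed by -0.05 (adjusted p = 0.88), or by -0.417 with a common median (adjusted p = 0.0493, the lowest over the alternatives). Sterol synthesis genes were lower for 15 and higher for 0 of 28, or 16 and 1 adjusted over the list alone (adjusted p = 7.9e-06), among them SQLE (-1.0 ± 0.09) and MSMO1 (-0.88). Interferon genes were higher for 10 and lower for 1 of 26, or 11 and 2 adjusted over the list alone (adjusted p = 0.00192, and adjusted p = 0.0955 with an estimated correlation), such as IFITM1 (1.6, detected on 1 of 3 empty-vector arrays). Hypoxia genes were lower for 13 and higher for 3 of 27, or 17 and 3 adjusted over the list alone (adjusted p = 0.00183), with ENO2 at -1.66.

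Further lists lay close to the threshold between PR-B and empty-vector cells. Stress genes were lower for 8 and higher for 2 of 25, or 9 and 3 adjusted over the list alone (adjusted p = 0.0259, and adjusted p = 0.47 with an estimated correlation), with VLDLR, detected on 2 of 3 PR-B arrays, at -1.16. MAPK genes were lower for 7 and higher for 0 of 25, or 9 and 1 adjusted over the list alone (adjusted p = 0.0458, and adjusted p = 0.163 with an estimated correlation), with SPRY2 at -0.66. Decidualization genes were lower for 6 and higher for 0 of 21, also 6 and 0 adjusted over the list alone (adjusted p = 0.0468, and adjusted p = 0.0955 with an estimated correlation), with STC1, a secreted glycoprotein, at -2.43. These calls were lost without empty-vector vehicle array 2 or 3, with adjusted p from 0.0511 to 0.0912, the MAPK call also without PR-B vehicle array 3 (0.0624) and the decidualization call without PR-B vehicle array 2 or 3 (0.0735 and 0.0611). Over all alternatives the adjusted p ran from 0.00145 to 0.1, from 0.00279 to 0.115 and from 0.0124 to 0.346. In total 1755 genes were higher and 1864 lower. With a common median 5503 were called, 451 higher and 5052 lower, as the median of all genes moved by -0.224. The vehicle differences of PR-A and PR-B cells from the same empty-vector arrays correlated at 0.13 across genes (simulated 0.499), with a covariance of 0.0191 (simulated 0.0109). The pair had 429 genes higher and 508 lower in common and 620 opposite. For independent lists 227.7 and 252 were computed for the first 2 counts, and part of the excess may come from the shared controls. The number of opposite calls for independent lists was not computed, so these counts do not show a shift shared by the clones. The simulated overlap of 0 is no yardstick, since the simulated groups were unchanged.

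Set against PR-A cells in vehicle, PR-B cells had more of the pluripotency-associated gene DPPA4 (4.39), CLDN11 (3.55), THY1 (3.53, at least 9.63-fold) and DSG2 (3.47). DPPA4 and DSG2 were detected on 2 of 3 PR-A arrays. PR-B cells had less CTSK (-4.59, at least 17.5-fold), SLC16A3 (-4.32, detected on 2 of 3 PR-B arrays), the growth factor gene MDK (-3.93), IGFBP1 (-3.87, at least 11.5-fold) and TFAP2C (at least 10.4-fold). FOXO1, detected on 1 of 3 PR-A arrays, was higher by 1.57 (adjusted p = 5.02e-08, or 0.61 without background correction) and CDKN1A by 1.98 (adjusted p = 1.35e-07). Of the 18 lists the hypoxia list passed, with 15 of 27 genes lower and 2 higher, or 17 and 2 adjusted over the list alone (camera adjusted p = 2.01e-05), among them ENO2 (-2.29) and CA12 (at least 3.24-fold lower). There were 3055 genes higher and 3076 lower, or 1608 and 3446 with a common median.

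Under R5020, PR-B cells had more GZMA (5.35, at least 29.7-fold), CD24 (5.03), KYNU, an enzyme of tryptophan breakdown (4.74 ± 0.07, at least 20.5-fold, adjusted p = 3.5e-17), and ANGPTL4 (4.53) than PR-A cells. CD24 and ANGPTL4 were detected on 2 of 3 PR-A arrays. PR-B cells had less CRISPLD2 (-5.02, 32.5-fold), CTSK (-4.62, detected on 1 of 3 PR-B arrays), VCAM1 (-3.76) and CA12 (at least 9.53-fold). FOXO1, detected on 2 of 3 PR-A arrays, was higher by 3.06 (adjusted p = 6.28e-12, or 1.621 without background correction) and CDKN1A by 3.46 (adjusted p = 6.68e-11). FOXO targets were higher for 19 and lower for 5 of 33, also 19 and 5 adjusted over the list alone (camera adjusted p = 0.00103), with GABARAPL1 at 2.26 and, below, IGFBP1 at -2.08. S phase genes were lower for 31 and higher for 1 of 38, or 33 and 1 adjusted over the list alone (adjusted p = 1.11e-10, and adjusted p = 0.00986 with an estimated correlation), with CDT1 at -1.48. Mitosis genes were lower for 23 and higher for 2 of 35, or 25 and 2 adjusted over the list alone (adjusted p = 9.6e-06, and adjusted p = 0.00194 with an estimated correlation), with PLK1 at -1.01. Progestin and glucocorticoid genes were higher for 14 and lower for 6 of 30, or 15 and 6 adjusted over the list alone (adjusted p = 0.0108, and adjusted p = 0.0511 with an estimated correlation), with KLF9 at least 9.03-fold higher. Hypoxia genes were lower for 16 and higher for 5 of 27, or 17 and 5 adjusted over the list alone (adjusted p = 0.00025), with ENO2 at -3.36. In total 3117 genes were higher and 3298 lower, or 3114 and 2075 with a common median.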

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

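In this part, the splits of 12 arrays that ignored the clones were chosen only after splits within clones had been seen. The response to R5020 differed between clones by a direct test for 1648 genes between PR-B and PR-A cells, 957 between PR-A and empty-vector cells and 2170 between PR-B and empty-vector cells. For 90 genes, R5020 changed expression in opposite directions in PR-A and PR-B cells. As groups, progestin and glucocorticoid genes (mean difference 0.507), FOXO targets (0.491), sterol synthesis genes (0.202) and epithelial genes (0.474) responded more upwards in PR-B than in PR-A cells. The sterol and epithelial calls, which rest on 4 of 28 and 2 of 8 genes, were lost with an estimated correlation (adjusted p = 0.0965 and adjusted p = 0.148 with an estimated correlation). The mean of the sterol list in PR-B against PR-A cells was -0.217 in vehicle (camera adjusted p = 0.0707). Under R5020 it was -0.015 (camera adjusted p = 0.818), so the larger rise in PR-B cells went with a lower start. S phase genes (-0.57) and mitosis genes (-0.438) responded more downwards. Outside the named genes, 1764 probes without a gene symbol passed the detection filter. R5020 changed 50 of them in PR-B cells (20 higher, 30 lower) and 32 in PR-A cells (11 higher, 21 lower), against 0 in empty-vector cells.

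The lower cell-cycle genes of PR-B cells, which shifted as a block, were examined for a technical reading. Over both lists (73 genes) the response differed by -0.507. Normalization as the whole source is argued against, because under 4 other normalizations the value nearest 0 was -0.287, where the median of all genes was 0.142. A single array is argued against too, as the value nearest 0 with 1 of 12 arrays left out was -0.486. A higher start in PR-B vehicle cells would need a vehicle difference of about the same size, and it was 0.043. Clone and isoform are confounded, and growth itself was not analysed here.

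Other splits of the arrays were tried for each count of genes. For 3 against 3 arrays only 10 splits exist, too few for a share under 0.05. In empty-vector cells 10 of the 10 splits gave as many genes as the real one (0, highest other 0). In the other 6 such comparisons 1 of the 10 splits, the real one, gave as many. The real counts were 2311 for R5020 in PR-A cells, 3867 for R5020 in PR-B cells, 4299, 3619 and 6131 for the vehicle comparisons, and 6415 under R5020. The highest other split gave 1 gene for R5020 in PR-B cells and 0 for the rest. For differences in response, 100 splits of 12 arrays into 4 groups were drawn. As many genes came from 2 of 100 for PR-B against empty vector (2170, highest other 3764), 10 of 100 for PR-A against empty vector (957, highest other 3636) and 15 of 100 for PR-B against PR-A (1648, highest other 3261). These splits mix arrays across clones and treatments and so carry real differences. A split that calls more genes than the real one therefore need not reflect chance. Splits that kept each array in its clone gave as many genes in 6, 6 and 8 of 100, in the order PR-A against empty vector, PR-B against empty vector and PR-B against PR-A. Their highest other counts were 1427, 2352 and 4134, also above the real ones. The share was under 0.05 only for PR-B against empty vector, and only with the splits that ignored the clones. Neither share measures chance alone, since splits of both kinds carry real differences, so neither excludes chance. The other within-clone splits with as many genes (5, 5 and 7) all kept the treatments apart in at least 1 clone, its labels being true or reversed. Splits that mixed treatments in both clones called at most 0, 1 and 0 genes.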

How the results depend on the processing

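No alternative here was chosen after the results were seen. Of 2520 list results under other settings 2351 kept the call or its absence (94 of them, called in neither fit, changed sign), 47 lost the call, 120 gained one and 2 changed sign with a call in 1 fit. Of 8888 results for named genes 8746 did so (3 uncalled with a changed sign), 136 lost the call and 6 gained one, and of 158 counts 147 stayed within 1.5 times. With 1 array left out, 1362 of 1404 list results, 5637 of 5826 gene results and all 126 counts were kept in this sense, 58 uncalled list results and 3 uncalled gene results among them with a changed sign. In empty-vector cells 1 gene passed with no background correction, with the authors' processed values and with trend and robust options. A common median gave 1422 genes for R5020 in PR-A cells, 5503 between PR-B and empty-vector cells in vehicle, 613 and 1348 for the PR-A and PR-B responses against empty vector, and 675 genes changed the same way in both clones. Under it the list of fibroblast, mesothelial and endothelial markers went to -0.001 between PR-B and empty-vector cells (adjusted p = 0.0354, range over alternatives to 0.607), and the S phase list to -0.034 in the PR-A response against empty vector (adjusted p = 0.487). That scaling moved the median of all genes to -0.218 and -0.11, so both lists stayed above it and neither turned relative to other genes. Fits on only the arrays compared, which have fewer residual degrees of freedom, gave 1061 genes for R5020 in PR-A cells and 674 changed the same way in both clones. Fry, which does not compare a list with other genes, called 116 list results against 60, and an estimated correlation 40. The replicate numbers did not pair the arrays: deviations of same-numbered arrays correlated from -0.182 to 0.189, with 3 of 45 pairs over 0.1. With the number as a replicate block the counts were 2201 and 3754 for R5020 in PR-A and PR-B cells, 4190, 3483 and 5964 in vehicle, 6343 under R5020, 882, 2059 and 1508 for the differences in response, and 0 in empty-vector cells. Of the list calls the block ended that of the epithelial list between the PR-B and PR-A responses (adjusted p = 0.0615), and 4 calls of named genes. Chip as a block was not run, as barcodes were not used here. Signal over background limits the folds of dim probes, which are bounds where undetected.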

Other observations

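In this part, the tests of Gene Ontology groups, with the genes named beside them, were chosen only after results had been seen, as was the comparison of the deviation of PR-A vehicle array 2 with those of other groups. Of 437 terms of the array annotation, 31 passed in the PR-B response to R5020, 17 in the difference between the PR-B and PR-A responses, and 0 in PR-A and 0 in empty-vector cells. In PR-B cells 27 of 100 genes of messenger RNA splicing were lower and 1 higher (camera adjusted p = 0.000481, and adjusted p = 0.0376 with an estimated correlation), among them HNRNPA1 and DDX39A. Ribosomal RNA processing had 20 of 60 lower and 1 higher (adjusted p = 0.00663), including EXOSC5, a subunit of the RNA exosome. DNA repair had 39 lower and 11 higher of 132 (adjusted p = 0.0168), with BRCA1 and RAD54L in its branch of homologous recombination.

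Other groups had more genes higher than lower in PR-B cells, in calls that an estimated correlation ended. Vesicle transport had 36 genes higher and 11 lower of 139 (adjusted p = 0.00962, and adjusted p = 0.0871 with an estimated correlation). Antigen presentation by MHC class I had 5 of 10 higher and 0 lower (adjusted p = 0.0132, and adjusted p = 0.116 with an estimated correlation), among them HLA-E and B2M. Cell-matrix adhesion responded more in PR-B than in PR-A cells, with 11 of 39 genes higher and 1 lower (adjusted p = 0.000165, and adjusted p = 0.12 with an estimated correlation), including the integrin genes ITGAV and ITGB1.

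Across genes, the vehicle difference of 1 receptor clone from empty vector correlated weakly with the R5020 response of the other clone, at 0.119 for PR-B in vehicle with the PR-A response and 0.101 for PR-A in vehicle with the PR-B response. Within a clone, where the vehicle arrays enter both comparisons, the correlation was -0.067 for PR-A (covariance -0.0091, simulated -0.011) and -0.08 for PR-B (covariance -0.0114, simulated -0.0109), so the vehicle clones did not lie along their own response beyond a small excess in PR-A cells. No array enters both of the crossed comparisons, so shared arrays could not be their source whatever the size of the correlation. The test set for that reading therefore decided nothing. With 1 array left out the crossed values ran from 0.068 to 0.147. The bound used in that test, 0.05, which the reading of shared arrays allowed, was put in place of the bound written beforehand, above 0.1, only after the values had been seen. Both values met the earlier bound, but not with every array left out. Within 3 classes of genes by mean signal the lowest crossed value was 0.047, from 0.017 to 0.05 with arrays left out, so a part played by the signal level of the probes cannot be told apart from other sources.

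Among the arrays, PR-A vehicle array 2 stood furthest from its group, with a deviation SD of 0.2092 against at most 0.174 elsewhere and an array weight of 0.274. CDKN1A stood at 6.2 on it, and at 7.01 and 7.2 on the other PR-A vehicle arrays. A wrong label is argued against: its lowest correlation with its own group was 0.9889 and its highest with another group 0.9825. Its deviation had a rho of -0.032 with mean signal. Quantile normalization largely removes such a trend beforehand, so this value does not decide on signal level. Probe GC content could play a part (rho -0.262, where other arrays ran from -0.199 to 0.21), and its deviation correlated at 0.285 and 0.262 with those of empty-vector vehicle array 1 and empty-vector R5020 array 3, whose rho with GC were -0.199 and -0.142. With arrays of other groups the correlation ran down to -0.225. Part of the deviation may thus be shared between clones, but as the rho stayed under the 0.3 set beforehand, GC content cannot be told apart from a difference between cultures. No biological explanation was tested.

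A weak R5020 response without introduced receptor was tested as a hypothesis. In empty-vector cells the genes that rose in PR-B cells exceeded those that fell by 0.0203, from 0.0164 to 0.0247 with arrays left out, against 1.2854 in PR-B cells. Camera with an estimated correlation gave p = 0.23 and 0.674 for the risers and the fallers, so the test did not show such a response.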
